A study of Mus musculus with 74 samples.

How the data were processed

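Whole brains of 37 mice were dissociated, and viable Cd11b-positive cells (microglia) and all other viable cells (nonmicroglia) were sorted, per the labels. The labels give each library's fraction, diet, weeks, Trem2 genotype, sex and animal number. RNA of each fraction was made into 3' tag libraries with a low-input kit, so that most tags lie near the 3' end of a transcript. The deposited table holds counts of tags per gene as whole numbers for 49912 genes and 74 libraries, with a symbol, a biotype and an Ensembl identifier per gene, and no normalization. The submitters' processing notes name FastQC 0.11.5, STAR, MultiQC, R 3.4.3 and the assembly GRCm38.p6. The counter, the annotation, the use of strand and of molecular identifiers are not given in the sources used here. Overlapping genes and close paralogs can therefore share counts. Coordinates are from the GENCODE M21 annotation, matched by Ensembl identifier.

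Libraries held 1043961 to 3945694 counts (median 1753725). An RNA integrity number was given in the labels for part of the libraries and was not used in a model. No library was left out. Over the 2701 pairs of libraries, the lowest chi-square per degree of freedom between count profiles was 8.96, so that no library was a copy of another. Both fractions of an animal share its number. In wild-type controls, the correlations of the fractions' deviations from their group means across genes were 0.001, -0.0147, 0.0135, 0.0604 and -0.0147 for animals 1930, 1932, 309, 5512 and 9145.

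Each fraction was analysed apart with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, TMM gave the normalization, and a robust quasi-likelihood model had 12 group means and sex. Standard errors were derived from the quasi-likelihood F statistic. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with calls at an adjusted p under 0.05. Tests were two-sided. The comparisons were diet within genotype and week, knockout and heterozygote against wild type within diet and week, the interaction of diet and genotype (knockout against wild type) at each week, and microglia against nonmicroglia in wild-type controls with week and sex as covariates: 33 in all. These, the gene lists, the named-gene rule and most alternative settings were fixed before the data were examined. Added afterwards were 2 comparisons, knockouts against heterozygotes on cuprizone at 12 weeks and the matching interaction, and 2 alternatives named below.

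The 29 gene lists held 15 programs and 14 cell types, fixed from general knowledge. Some genes stand on several lists, for example in the homeostatic and microglia lists. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated one, adjusted over the lists of a comparison. Members were counted as called over all genes and adjusted over the list alone. Of 957 list tests 195 passed with the preset and 78 with an estimated correlation. A fitted fold change of a gene at 0 in a whole group depends on the prior count. With such members held at a floor of 3 counts over the group, 1.12 was the largest move of the median of a list that passed camera in a comparison of 2 groups. In interactions such members were left out instead, and medians moved as well. That of the efflux list at 12 weeks (knockout against wild type in microglia) moved from -1.14 to -0.53.

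Genes named in the text are Trem2, a fixed panel of disease-associated, homeostatic, myelin, astrocyte, precursor and endothelial genes, and for each comparison the 5 largest rises and 5 largest falls with adjusted p under 0.05, an average log2 CPM of at least 3 and no overlap between groups (not asked of interactions). For each list they are up to 4 called members with the largest change, or else the member with the smallest p. Some panel genes are not reported here. Predicted genes and sex-linked genes were left out of the rule. The genes Map1a, 2410006H16Rik and the remaining members of short sets of calls lie outside it and were chosen after their values were seen.

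The alternatives planned were DESeq2 size factors, the DESeq2 1.42.0 Wald test (with a local dispersion trend in the nonmicroglia fraction, where the parametric trend was at the edge of convergence, a choice made after the fit was seen), limma voom with quality weights, no filter on low counts, no sex term, leaving out each library in turn, an animal block in the fraction comparison and an estimated correlation. Added after the data were seen were the share of counts on genes that do not code for protein as a covariate, and leaving out the libraries beyond 30 on principal component 1 of log2 CPM (genes averaging over 5). Other splits of the libraries were counted in every comparison with at least 3 animals per group, all of them or 100 drawn at random. The code was tested on independent genes simulated at library depths. In a microglia comparison 3 of 83 calls were false (12992 genes), and in a nonmicroglia one 2 of 79 (15823). A raised list was found in both and 0 others called, with correlated lists untested.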

Results

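Cuprizone is a copper chelator that kills mature oligodendrocytes when it is mixed into the chow, so that feeding it strips myelin from axons and leaves myelin debris for microglia to clear. Trem2 encodes a receptor through which microglia sense lipids and debris. The study fed chow with 0.2% cuprizone, or control chow, to wild-type, Trem2 heterozygous and Trem2 knockout mice for 5 weeks (acute demyelination) or 12 weeks (chronic demyelination). It asked how microglia and the other brain cells respond when the receptor is reduced or missing. Viable cells of each whole brain were sorted into Cd11b-positive cells, called microglia here, and all other cells, called the nonmicroglia fraction. Both fractions of each of 37 animals were sequenced with a 3' tag method, which gave 74 libraries. Each fraction had 12 groups of 3 animals, except that both heterozygote groups at 12 weeks had 4 and wild type on control chow at 12 weeks had 2. Every group had 1 male, and the other animals were female. Libraries held 1043961 to 3945694 counts in microglia (median 1782314) and 1255465 to 3441041 in the nonmicroglia fraction (median 1705753). Levels are in counts-per-million (CPM), and a level of 1 rests on 1 to 4 counts. After the filter on low counts, 14087 genes were tested in microglia and 16915 in the nonmicroglia fraction. Levels are given as mean ± SD over animals, and differences are log2 fold changes ± standard error (SE). Adjusted p-values of genes are from edgeR unless another tool is named, and those of lists from camera. A single value in brackets after a difference is its adjusted p.

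Trem2 (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147 on the GRCm38.p6 assembly) was lower in knockout than in wild-type microglia in all 4 settings. On control chow at 5 weeks it stood at 677 ± 247 CPM in wild type, 379 ± 31.5 in heterozygotes and 160.2 ± 84.1 in knockouts (n = 3 each). On cuprizone it stood at 730.0 ± 285, 725 ± 284 and 198 ± 13.1 (n = 3 each). At 12 weeks the levels were 802 ± 139 (n = 2), 349 ± 56.4 (n = 4) and 145 ± 58.9 (n = 3) on control chow. On cuprizone they were 962 ± 121 (n = 3), 918 ± 139 (n = 4) and 157 ± 75.5 (n = 3). The knockout differed from wild type by -2.07 ± 0.33 on control chow and -1.88 ± 0.33 on cuprizone at 5 weeks (adjusted p = 0.000945 and 0.00103). At 12 weeks it differed by -2.45 ± 0.36 and -2.62 ± 0.34 (adjusted p = 9.98e-05 and 1.19e-06). Heterozygotes differed from wild type by -0.83 ± 0.32 and -1.19 ± 0.33 on control chow, which did not pass the test (adjusted p = 0.988 and 0.348). Within heterozygotes Trem2 rose with cuprizone at 12 weeks by 1.40 ± 0.28 (adjusted p = 0.0012). Knockout libraries still held 155 to 786 Trem2 counts each. The tags lie at the 3' end of the transcript, and if the deleted part lies elsewhere in the gene they do not check the genotype labels. At 5 weeks on control chow the knockout difference was -1.84 without knockout animal 1104, -1.72 without wild-type animal 5512 and -1.90 without knockout animal 9470, with adjusted p = 0.0625, 0.118 and 0.122.

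**Figure D1:**
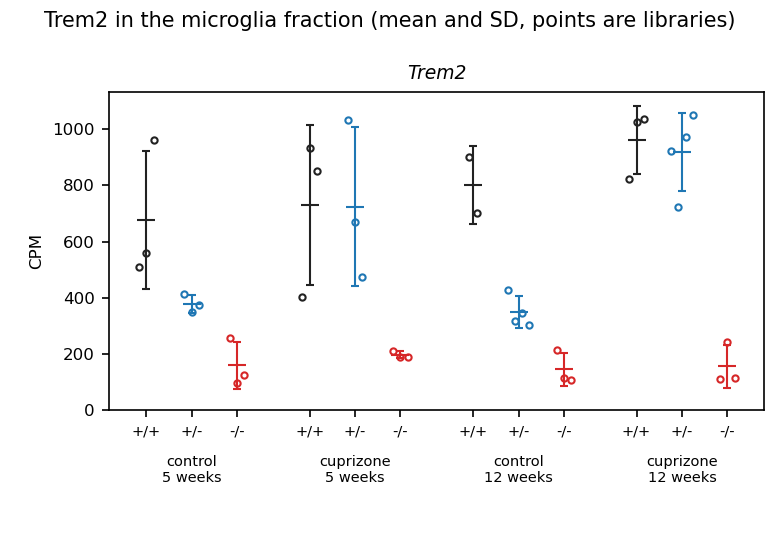
Trem2 in the microglia fraction, in CPM, by diet, weeks and genotype (+/+ wild type, +/- heterozygote, -/- knockout); points are libraries, bars the mean and SD. Knockout means lie between 145 ± 58.9 and 198 ± 13.1 CPM (SD, n = 3), and the wild-type mean on cuprizone at 12 weeks is 962 ± 121 CPM (SD, n = 3).

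The sort was examined in wild-type mice on control chow (5 animals, both fractions). Microglial and homeostatic genes were far higher in the Cd11b-positive pool. Cx3cr1, the fractalkine receptor, stood at 17250.5 ± 2891 against 176 ± 43.4 CPM (n = 5 each). P2ry12, a purinergic receptor of resting microglia, was at 2799 ± 1267 against 40.2 ± 9.43, and Tmem119, a microglia marker, at 1130.0 ± 172 against 14.4 ± 6.99 (n = 5 each). Myelin genes were far lower there, with a list median of -5.01. Of 10244 genes tested, 1584 were higher and 2012 lower in microglia. Higher in microglia were all 12 microglia, all 17 homeostatic, all 12 inflammatory, 8 of 9 complement and 13 of 15 antigen presentation genes. So were 20 of 27 lysosome (2 lower), 12 of 21 disease-associated (2 lower) and 19 of 21 immediate early and heat shock genes (1 lower). The counts adjusted over the list alone were 12, 17, 12, 8, 13, 21, 12 and 20. These lists passed camera with both a preset and an estimated correlation, with adjusted p of at most 0.0342 in the second setting, for the disease-associated list. Markers of other myeloid cells were higher in that pool too, with all 8 border macrophage markers, all 6 neutrophil markers and 2 of 3 monocyte markers called. These counts were the same adjusted over the list alone. With an estimated correlation camera gave the border macrophage list adjusted p = 0.014, the neutrophil list 0.107 and the monocyte list 0.16. Ngp, a neutrophil granule gene, stood at 288 ± 265 against 1.14 ± 0.717 CPM and Mrc1, the mannose receptor of border macrophages, at 289.8 ± 106 against 2.51 ± 1.18. Lower in microglia were 18 of 19 mature oligodendrocyte, 4 of 8 newly formed oligodendrocyte (2 higher), 7 of 7 precursor, 14 of 14 astrocyte and 11 of 11 endothelial markers. The others of this kind were 8 of 8 mural, 8 of 9 neuronal, 5 of 5 ependymal and choroid plexus, 1 of 1 lymphocyte and 1 of 1 erythroid markers. These counts did not change adjusted over the list alone. The newly formed oligodendrocyte, lymphocyte and erythroid lists did not pass camera with the preset correlation either, and the others of this group did. With an estimated correlation the adjusted p was 0.0516 for mature oligodendrocytes, 0.561 for newly formed ones, 0.0516 for precursors, 0.0184 for astrocytes and 0.0659 for endothelium. It was 0.0278 for mural cells, 0.0659 for neurons, 0.0342 for ependyma, 0.266 for lymphocytes and 0.266 for erythroid cells. Cholesterol biosynthesis and uptake genes were lower in microglia (10 of 20, 12 adjusted over the list alone, adjusted p = 0.0208 with an estimated correlation). The remaining lists passed camera in neither setting. They were cholesterol efflux (4 higher and 2 lower of 15), fatty acid (1 and 8 of 17), and interferon (3 and 1 of 15). The last of them were proliferation (1 and 0 of 6), glycolysis (1 and 3 of 11), reactive astrocyte (2 and 2 of 6) and integrated stress response (4 and 5 of 15). Median and mean of the last list were 0.52 and -0.17, and of the reactive astrocyte list -0.38 and 0.60, with camera pointing up in both.

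In wild-type microglia, 5 weeks of cuprizone raised the genes of the disease-associated state, in which microglia take up and digest lipid-rich debris. Apoe, an apolipoprotein that carries cholesterol out of cells (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188), rose by 2.01 ± 0.25 to 6309.9 ± 947 CPM from 1599.9 ± 379 (adjusted p = 8.04e-07). Lpl, a lipase that frees fatty acids from lipoproteins (ENSMUSG00000015568.16, chromosome 8, 68880491 to 68907448), rose by 4.28 ± 0.50 to 1478 ± 328 CPM (adjusted p = 9.58e-06). Cst7, an inhibitor of lysosomal proteases (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944), rose by 4.40 ± 0.56 to 643 ± 90.8 (adjusted p = 2.85e-05). Clec7a, a pattern receptor (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779), rose by 2.92 ± 0.35 (adjusted p = 4.4e-07). Axl, a receptor for dying cells, rose by 2.53 ± 0.46 (adjusted p = 0.00279) and Mmp12, a macrophage elastase, by 3.19 ± 0.74 (adjusted p = 0.0446; n = 3 and 3 throughout). Spp1, the matrix protein osteopontin, was at 719 ± 421 against 13.3 ± 10.6 CPM and Itgax, an integrin, at 188 ± 52.9 against 23.3 ± 8.69. Neither passed the test (adjusted p = 0.0584 and 0.051). Apoc1, an apolipoprotein, rose from 0 to 27.7 ± 18.4 CPM. Of 21 disease-associated genes 7 rose and 14 did not pass, and 18 rose adjusted over the list alone. The list median was 2.01 (adjusted p = 2.13e-48, and adjusted p = 1.66e-07 with an estimated correlation). The interferon list had a median of 1.56 with 0 genes called over all genes and 12 of 20 adjusted over the list alone. The proliferation list had a median of 2.29 with 0 and 3 of 22 (adjusted p = 0.000929 and 0.00128 with an estimated correlation). Lysosome, glycolysis, cholesterol efflux and antigen presentation genes rose as lists, with medians of 0.41, 1.29, 0.55 and 0.76. With genes at 0 in a group held at the floor, the glycolysis median was 1.05. Of their members 1, 0, 2 and 1 were called, among them the protease Ctsb (1.18 ± 0.23) and the MHC class I chain B2m (1.39 ± 0.28). Adjusted over the list alone 8, 3, 3 and 5 rose (adjusted p = 0.00065, 0.00128, 0.00158 and 0.0367 with an estimated correlation). The homeostatic list fell, with a median of -0.41 and 0 genes called by edgeR or adjusted over the list alone (adjusted p = 0.0254 with an estimated correlation). Mitochondrial genes took a mean of 3.54% of counts on cuprizone and 2.35% on control chow (n = 3 each). In all, 20 genes rose and 0 fell by edgeR, and 961 had an unadjusted p under 0.05. DESeq2 and limma called 79 and 86. The count was 13, 8 and 11 without control animals 1930, 309 and 5512, and 10 and 10 without cuprizone animals 2474 and 9144.

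In heterozygous microglia 5 weeks of cuprizone also raised disease-associated, lysosomal and interferon genes. Apoe rose by 2.46 ± 0.26 (adjusted p = 3.73e-09), Lpl by 4.73 ± 0.52 (1.35e-06) and Cst7 by 4.83 ± 0.57 (4.41e-06; n = 3 and 3). Clec7a rose by 2.79 ± 0.35 (5.27e-07), Itgax by 3.81 ± 0.68 (0.00477) and Spp1 by 5.76 ± 1.27 (0.0462). Among 21 disease-associated genes 12 rose, 19 adjusted over the list alone, with a median of 2.41 (adjusted p = 4.4e-07 with an estimated correlation). Lysosomal genes rose (4 of 28, 10 adjusted over the list alone, median 0.58), among them the proteases Ctsb, Ctsd and Ctsz and the membrane protein Cd63. So did interferon genes (3 of 20, 11 adjusted over the list alone, median 2.09), among them Isg15, Ifitm3 and Ifi27l2a. Both lists held (adjusted p = 0.000288 and 0.000288 with an estimated correlation). In the proliferation list Top2a, the mitotic topoisomerase, rose by 2.87 ± 0.66 and 6 genes rose adjusted over the list alone. In the glycolysis list Pkm and Gpi1 rose, and 6 adjusted over the list alone. The list medians were 2.63 and 1.27 (adjusted p = 0.000288 and 0.000304 with an estimated correlation). The homeostatic list fell (median -0.47, 0 genes called by edgeR over all genes and 4 adjusted over the list alone, adjusted p = 0.00361 with an estimated correlation). Jun, an immediate early gene, fell by 1.13 (SE 0.22, adjusted p = 0.00492), and its list had a median of -0.65 and adjusted p = 0.0775 with an estimated correlation. The other gene that fell was Adrb1, the beta-1 adrenoceptor (-1.70 ± 0.38). Mitochondrial genes took 3.33 ± 0.715% of counts on cuprizone and 2.25 ± 0.244% on control chow (SD, n = 3 each). By edgeR 37 genes rose and 2 fell. DESeq2 called 107 and limma 70. Without control animals 9546, 4352 and 1745 the total was 13, 16 and 25, and without cuprizone animal 1106 it was 23.

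Knockout microglia at 5 weeks raised part of these genes. Cst7 rose by 3.42 ± 0.55 (adjusted p = 0.00267) to 166 ± 96.1 CPM, Clec7a by 2.16 ± 0.36 (0.000573) to 101 ± 11.4 and Apoe by 1.57 ± 0.25 (0.000406) to 3309 ± 1546 (n = 3 and 3). Lpl was at 40.5 ± 19.3 CPM on cuprizone and 36.6 ± 13.9 on control chow, a difference of 0.13 ± 0.46 (adjusted p = 1). Of 21 disease-associated genes 3 rose, 10 adjusted over the list alone, and the median was 1.28 (adjusted p = 0.00629 with an estimated correlation). Lysosome, cholesterol efflux, interferon, proliferation, glycolysis and inflammatory genes rose as lists, with medians of 0.37, 0.68, 1.22, 1.47, 0.78 and 0.61. Over all genes edgeR called 1 of their members, Apoe. Adjusted over the list alone 5, 3, 2, 1, 0 and 5 rose. With an estimated correlation the lists had adjusted p = 0.00629, 0.0109, 0.043, 0.0186, 0.02 and 0.0381. With genes at 0 in a group held at the floor, the efflux and proliferation medians were 0.60 and 1.32. H2-D1, an MHC class I gene that shares sequence with its family, rose by 1.90 ± 0.36 (adjusted p = 0.00529), and Zfas1, a noncoding RNA, by 2.26 ± 0.35 (adjusted p = 0.000406). Mitochondrial genes took 3.49 ± 0.612% of counts against 2.11 ± 0.211% on control chow (SD, n = 3 each). EdgeR called 8 genes up and 0 down, DESeq2 36 and limma 2. With no count filter edgeR called 61, beside 67 in wild type and 90 in heterozygotes. The filtered total was 4 without control animal 1104, control animal 945 or cuprizone animal 310.

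Set against wild type at 5 weeks on cuprizone, knockout microglia were lower in Lpl and other disease-associated genes. Lpl stood at 40.5 ± 19.3 against 1478 ± 328 CPM (adjusted p = 1.02e-06; n = 3 and 3). Slamf8, a cell surface receptor of myeloid cells, differed by -4.01 ± 0.57 (1.76e-05), Clec7a by -2.48 ± 0.35 (1.38e-05), Ank, a pyrophosphate transporter, by -2.36 ± 0.48 (0.0235) and Axl by -2.14 ± 0.45 (0.0318). Apoe was at 3309 ± 1546 against 6309.9 ± 947 CPM and Cst7 at 166 ± 96.1 against 643 ± 90.8, and neither passed the test (adjusted p = 0.167 and 0.261). Of 21 disease-associated genes 5 were lower and 15 adjusted over the list alone, with a median of -1.72 (adjusted p = 2.04e-06 with an estimated correlation). The homeostatic list was higher in knockouts, with a median of 0.55, 0 genes called by edgeR over all genes and 4 adjusted over the list alone (adjusted p = 0.000738 with an estimated correlation). EdgeR called 0 genes higher and 11 lower, DESeq2 34 and limma 40. The count was 6 without knockout animal 8485 and 7 without wild-type animal 2474 or 9144. On control chow Trem2 itself was the 1 gene called by edgeR, 610 had an unadjusted p under 0.05, and DESeq2 called 3 and limma 1. The count was 0 without knockout animal 1104 or 9470 or wild-type animal 5512, and 2 without knockout animal 945. The test of whether the diet response differed between knockout and wild type called 1 gene, Lpl, at -4.15 ± 0.66 (adjusted p = 0.0101). There were 640 genes at an unadjusted p under 0.05, and DESeq2 and limma called 3 and 4. The edgeR count was 0 without wild-type animal 5512 or 9144 or knockout animal 945 and 2 without knockout animal 1104 or 9470. For the disease-associated list this interaction had a median of -0.76, adjusted p = 0.000132 with the preset and adjusted p = 0.26 with an estimated correlation. Between heterozygotes and wild type edgeR called 0 genes on control chow and 0 on cuprizone, with 662 and 600 at an unadjusted p under 0.05. DESeq2 called 1 and 1, limma 1 and 2, and edgeR with no count filter 8 and 0. On control chow 8 of 9 neutrophil markers were lower in heterozygotes adjusted over the list alone (median -3.40, adjusted p = 0.288 with an estimated correlation).

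After 12 weeks of cuprizone, wild-type microglia carried the disease-associated profile together with raised cholesterol export and storage genes and lowered homeostatic genes. Apoe rose by 3.66 ± 0.32 to 18580.5 ± 2307 CPM from 1396 ± 396 (adjusted p = 6.19e-12), and Lpl by 4.41 ± 0.61 to 2692 ± 534 (9.74e-05; n = 3 and 2). Clec7a rose by 3.53 ± 0.43 (2.92e-07), Itgax by 4.25 ± 0.82 (0.00654) and Igf1, a growth factor, by 4.89 ± 0.82 (0.0015). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 5.85 ± 1.34 (adjusted p = 0.0342). Spp1 was at 1210.4 ± 175 against 24.9 ± 2.67 CPM (adjusted p = 0.0763). Of 21 disease-associated genes 14 rose, 20 adjusted over the list alone, with a median of 3.15 (adjusted p = 1.4e-07 with an estimated correlation). In the cholesterol efflux list 5 of 19 genes rose, among them Abcg1, a sterol exporter (2.66 ± 0.63, adjusted p = 0.0226), and Soat1, which esterifies cholesterol for storage (1.44 ± 0.38, adjusted p = 0.0398). Adjusted over the list alone 11 rose and 1 fell (median 1.33, adjusted p = 5.38e-05 with an estimated correlation). Apoc1, an apolipoprotein of the same list, was at 0 CPM in both control libraries and 43.8 ± 19.0 on cuprizone. Lysosomal genes rose (4 of 28, 15 adjusted over the list alone, median 0.87, adjusted p = 1.11e-05 with an estimated correlation), with Cd63 up by 1.74 ± 0.26 and Gla, a glycolipid hydrolase, by 2.68 ± 0.58. Homeostatic genes fell, 5 of 18 over all genes and 10 adjusted over the list alone, with a median of -0.84 (adjusted p = 0.000438 with an estimated correlation). Tmem119 (ENSMUSG00000054675.5, chromosome 5, 113793729 to 113800516) fell from 1109 ± 102 to 261 ± 86.6 CPM (adjusted p = 1.13e-05). P2ry12 (ENSMUSG00000036353.13, chromosome 3, 59216272 to 59262871) fell from 1946 ± 1019 to 642 ± 113 (0.00297). Glycolysis genes had a median of 1.14 and fatty acid genes of 0.89, with 1 and 2 called and 3 and 4 adjusted over the list alone (adjusted p = 0.0158 and 0.0287 with an estimated correlation). Among the genes with the largest changes, Nup37, Arhgap19 and Lrmda were at 0 in both control libraries and at 21.2 ± 11.6, 14.1 ± 8.07 and 18.5 ± 7.70 CPM on cuprizone. EdgeR called 97 genes up and 38 down, and DESeq2 362. The control group had 2 libraries, and the total was 14 and 48 without animals 9145 and 1932 of that group. It was 66, 61 and 44 without cuprizone animals 1746, 8043 and 3917. Microglia of animal 9145, at 42.6 on principal component 1, stood apart from most libraries. With the share of counts on noncoding genes as a covariate the total was 38, and without the libraries beyond 30 on that component 25.

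Heterozygous microglia at 12 weeks, with 4 animals on each diet, changed in more genes than any other diet group: 265 rose and 94 fell by edgeR, and DESeq2 called 605. Apoe rose by 3.99 ± 0.24 to 18318 ± 1785 CPM (adjusted p = 2.91e-19), Cst7 by 4.70 ± 0.49 (1.21e-07), and Lpl by 4.64 ± 0.44 (3.1e-08; n = 4 and 4). Gpnmb rose to 402 ± 25.3 CPM from 6.65 ± 7.81 (0.000592), and Fabp5, a fatty acid carrier, by 6.09 ± 1.19 (0.00252). Chst2, a sulfotransferase, rose to 144 ± 30.3 CPM from 3.76 ± 2.15 (8.46e-09). Among 21 disease-associated genes 18 rose, 20 adjusted over the list alone, with a median of 3.27 (adjusted p = 8.73e-09 with an estimated correlation). Lysosomal genes rose (7 of 28, 15 adjusted over the list alone, median 0.64). Cholesterol efflux genes did so too (5 of 19, 6 up and 1 down adjusted over the list alone, median 0.44), with Npc2, which moves cholesterol out of lysosomes, up by 1.56 ± 0.20. The lists had adjusted p = 3.85e-05 and 0.0014 with an estimated correlation. In the inflammatory list 6 of 16 rose, 8 adjusted over the list alone, among them the cytokine Tnf and the chemokines Cxcl2 (1.51 ± 0.33) and Cxcl16 (2.12 ± 0.50). The list median was 0.77 (adjusted p = 0.0014 with an estimated correlation). Glycolysis (4 of 15, 8 adjusted over the list alone, median 1.65), fatty acid (4 of 20, 5, 0.77) and antigen presentation genes (4 of 16, 5, 0.65) rose as lists (adjusted p = 4.18e-05, 0.00709 and 0.0322 with an estimated correlation). Homeostatic genes fell (5 of 18 called, and 7 down and 1 up adjusted over the list alone, median -0.44, adjusted p = 0.0113 with an estimated correlation), among them Tmem119 (-1.40 ± 0.23) and Sall1, a transcription factor of microglial identity (-1.15 ± 0.20). Border macrophage markers Mrc1 and Cd163 fell, at 85.6 ± 35.6 against 233 ± 131 CPM and 94.3 ± 41.3 against 242 ± 70.7. Their list had adjusted p = 0.26 with an estimated correlation. Mitochondrial genes took 4.30 ± 0.244% of counts in these cuprizone libraries (n = 4) and 2.25 ± 0.762% in their controls (n = 4). On cuprizone the shares were 2.03 ± 0.463% and 2.48 ± 0.665% in wild type and knockouts (SD, n = 3 each).

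In knockout microglia 12 weeks of cuprizone raised 4 genes by edgeR and lowered 0. These were Apoe (2.03 ± 0.25, to 4264 ± 565 CPM, adjusted p = 1.13e-06), Clec7a (2.45 ± 0.35, 3.16e-05), Cst7 (3.32 ± 0.54, 0.00321) and Chst2 (3.53 ± 0.64, 0.00321; n = 3 and 3). Lpl was at 92.5 ± 33.6 against 28.3 ± 15.6 CPM (adjusted p = 0.359). The disease-associated list rose with 3 of 21 genes called, 13 adjusted over the list alone and a median of 1.67 (adjusted p = 0.000894 with an estimated correlation). So did the lysosome (0 and 7 of 28, median 0.32) and glycolysis lists (0 and 2 of 15, median 0.52, adjusted p = 0.00757 and 0.0401 with an estimated correlation). The homeostatic list had a median of -0.27, with 0 genes called by edgeR and adjusted p = 0.109 with an estimated correlation. Myelin genes had a median of 1.01 with 0 called and 2 of 17 up adjusted over the list alone. Astrocyte markers had a median of 0.76 (for the lists, adjusted p = 0.178 and 0.434 with an estimated correlation). DESeq2 called 37 genes and limma 7, and 1048 had an unadjusted p under 0.05. The edgeR count was 2 without control animal 1744 or 9467 and 7 without cuprizone animal 9542.

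**Figure D2:**
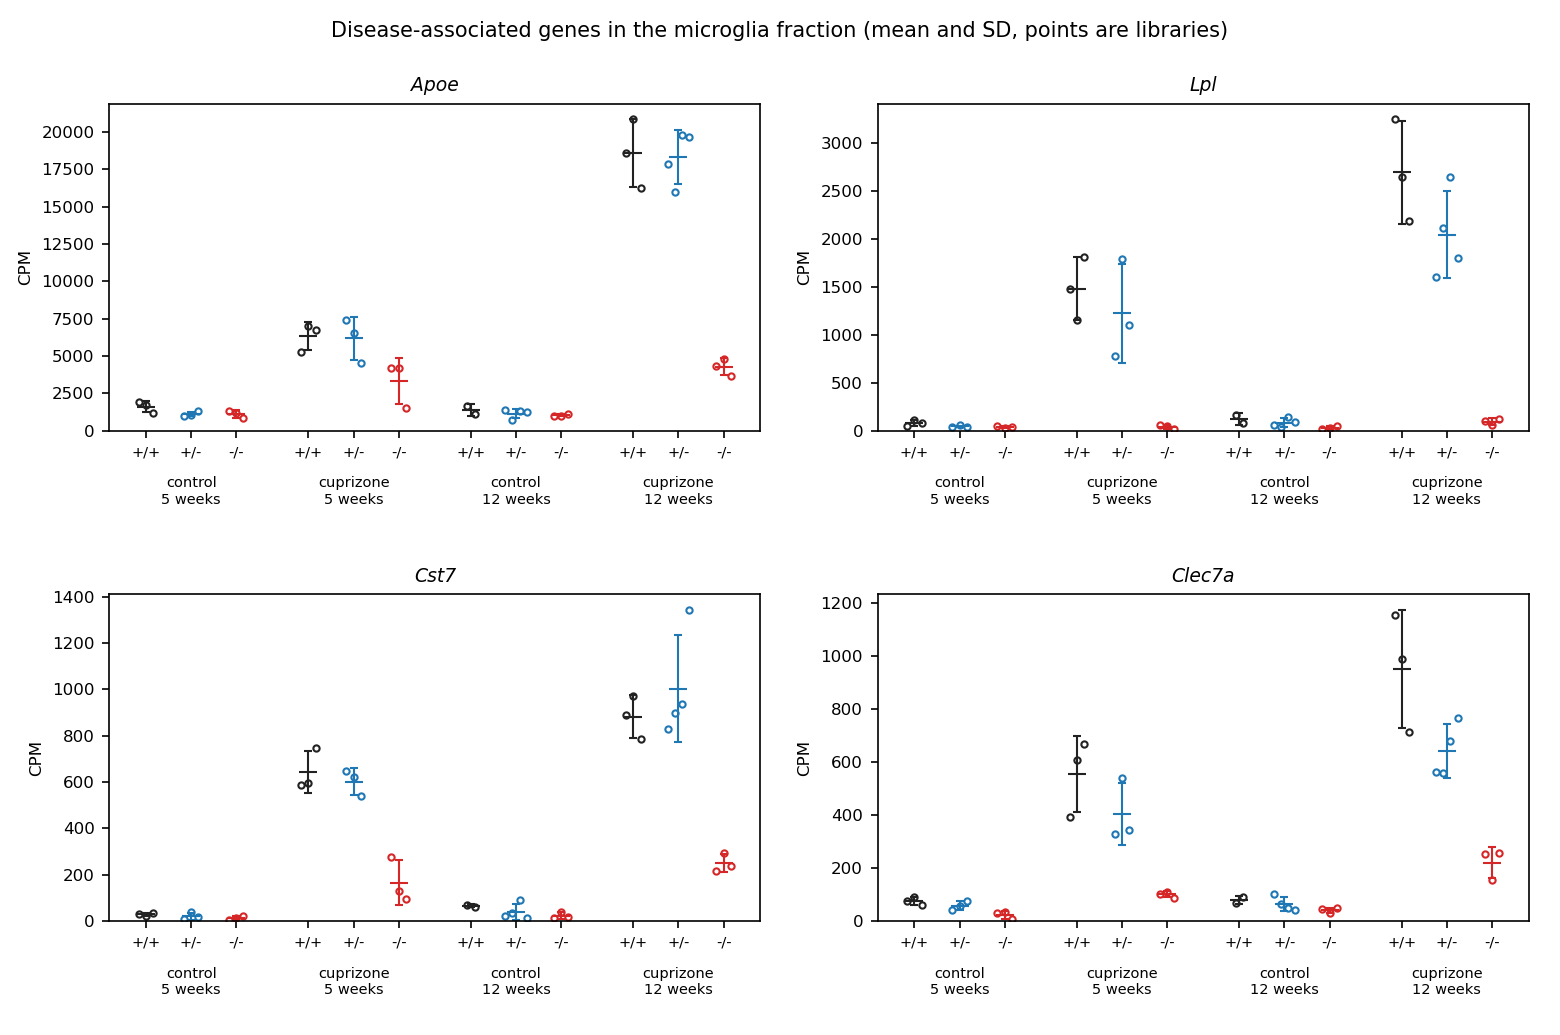
Apoe, Lpl, Cst7 and Clec7a in the microglia fraction, in CPM, by diet, weeks and genotype (+/+ wild type, +/- heterozygote, -/- knockout); points are libraries, bars the mean and SD. On cuprizone at 12 weeks Lpl is at 92.5 ± 33.6 CPM in knockouts, 2692 ± 534 in wild type (SD, n = 3 each) and 2041 ± 453 in heterozygotes (SD, n = 4).

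On cuprizone at 12 weeks knockout microglia were lower than wild type in Apoe, Lpl and the genes around them, and higher in genes of resting microglia. Apoe stood at 4264 ± 565 against 18580.5 ± 2307 CPM, a difference of -2.12 ± 0.26 (adjusted p = 3.1e-07). Lpl stood at 92.5 ± 33.6 against 2692 ± 534, a difference of -4.83 ± 0.52 (1.19e-06; n = 3 and 3). Also lower were Itgax (-3.57 ± 0.66, 0.00427), Axl (-2.47 ± 0.46, 0.00203) and Clec7a (-2.07 ± 0.34, 0.000235). So were Mmp12 (-3.71 ± 0.75, 0.00427), the transcription factor Bhlhe40 (-5.26 ± 1.14, 0.0107) and the chemokine Cxcl2 (-2.41 ± 0.39, 0.000214), while Spp1 and Cst7 did not pass the test (0.0838 and 0.106). Of 21 disease-associated genes 8 were lower, 19 adjusted over the list alone, with a median of -2.07 (adjusted p = 8.84e-08 with an estimated correlation). Lower as lists were also cholesterol efflux (2 of 19, Apoe and Soat1), lysosome (2 of 28, Cd63 and Ctsd) and glycolysis (0 of 15). Adjusted over the list alone 4, 7 and 2 were lower. The medians were -0.68, -0.47 and -0.87, with adjusted p = 0.000853, 0.000144 and 0.0499 with an estimated correlation. Fatty acid genes had a median of -0.49 (adjusted p = 0.0705 with an estimated correlation). Homeostatic genes were higher (2 of 18 called, 9 adjusted over the list alone, median 0.58, adjusted p = 0.00222 with an estimated correlation). P2ry12 was at 1736 ± 446 against 642 ± 113 CPM and Tmem119 at 741 ± 244 against 261 ± 86.6 (adjusted p = 0.000806 and 0.000806). Mbp, a myelin protein, was higher in the knockout libraries as well, at 281 ± 174 against 87.6 ± 17.3 CPM (adjusted p = 0.0311), with 472 CPM in animal 9542. Without that animal the difference was 0.96 (adjusted p = 0.36), and it did not pass without wild-type animal 1746, 3917 or 8043 either. The myelin list had a median of 1.33 and adjusted p = 0.285 with an estimated correlation. The microglia marker list had a median of 0.34 (adjusted p = 0.208 with an estimated correlation). EdgeR called 16 genes higher and 46 lower, DESeq2 193 and limma 110. The total was 33 and 40 without wild-type animals 3917 and 1746, and 40 without knockout animal 981, which lay at 35.5 on principal component 1.

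On control chow at 12 weeks edgeR called 3 genes between knockout and wild-type microglia, of which Trem2 was lower. Hspe1, a mitochondrial chaperonin, was at 74.0 ± 17.9 against 9.02 ± 6.84 CPM (adjusted p = 0.0418) and Supt4a, a transcription elongation factor, at 38.0 ± 30.5 against 0.698 ± 0.987 (n = 3 and 2). An unadjusted p under 0.05 was reached by 972 genes, and DESeq2 called 11 and limma 8. With no count filter edgeR called 69. The edgeR count was 1 without knockout animal 8635 or 9467 or wild-type animal 9145 and 6 without wild-type animal 1932. Between heterozygotes and wild type on control chow edgeR called 0 genes, or 73 with no count filter (1014 at an unadjusted p under 0.05, DESeq2 21, limma 1). On cuprizone 17 genes were higher in heterozygotes than in wild type and 0 lower. P2ry13 and P2ry12, purinergic receptors of resting microglia, stood at 1315 ± 87.0 against 365 ± 116 CPM and 1550.0 ± 88.2 against 642 ± 113 (adjusted p = 0.0106 and 0.0028). C1qc and C1qb, parts of complement C1q, were at 7228 ± 1129.9 against 2685 ± 121 and 1562 ± 303 against 707 ± 49.5 (adjusted p = 0.0204 and 0.0298; n = 4 and 3). Mt1, a metallothionein that binds metal ions, was higher by 2.02 ± 0.38 (adjusted p = 0.00534), while Apoe (-0.03 ± 0.23) and Lpl (-0.41 ± 0.41) did not pass (adjusted p = 1 and 0.849). The homeostatic list was higher (2 of 18, 7 adjusted over the list alone, median 0.54, adjusted p = 0.0335 with an estimated correlation). So was the microglia marker list (median 0.52, adjusted p = 0.0335), and neutrophil markers had a median of -2.12 (adjusted p = 0.467, both with an estimated correlation). These heterozygote libraries also had the higher mitochondrial share, with a lowest value of 4.05% against a highest of 2.56% in wild type. DESeq2 called 121 genes and limma 46. The edgeR count was 3 without wild-type animal 3917 or 8043, 11 without wild-type animal 1746, 9 without heterozygote 9469 and 30 without heterozygote 1040. It was 10 with sex left out of the model. The interaction of diet and genotype, knockout against wild type, called 4 genes, all with a lower diet effect in knockouts. They were Hspe1 (-4.83 ± 0.77, adjusted p = 0.000827), Cxcl2 (-3.33 ± 0.59, 0.00416), Prcp, a lysosomal peptidase (-3.62 ± 0.71, 0.0168), and Calhm2, an ion channel (-3.34 ± 0.66, 0.0168). Apoe was at -1.63 ± 0.38 (adjusted p = 0.0567). As lists, disease-associated and cholesterol efflux genes had a smaller diet response in knockouts, with medians of -1.63 and -1.14 (adjusted p = 0.0408 and 0.0408 with an estimated correlation). EdgeR called 0 and 0 of their members over all genes, and 9 and 4 were lower adjusted over the list alone. With genes at 0 in a group left out, the efflux median was -0.53. Homeostatic genes had a median of 0.59 and lysosomal genes of -0.50 (adjusted p = 0.0615 and 0.0615 with an estimated correlation). DESeq2 called 132 genes and limma 0. The edgeR count was 1 without wild-type control 9145, 2 without knockout 981 on cuprizone, 15 without knockouts 1744 on control chow or 1748 on cuprizone or wild-type control 1932, and 37 without knockout 9542 on cuprizone.

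**Figure D3:**
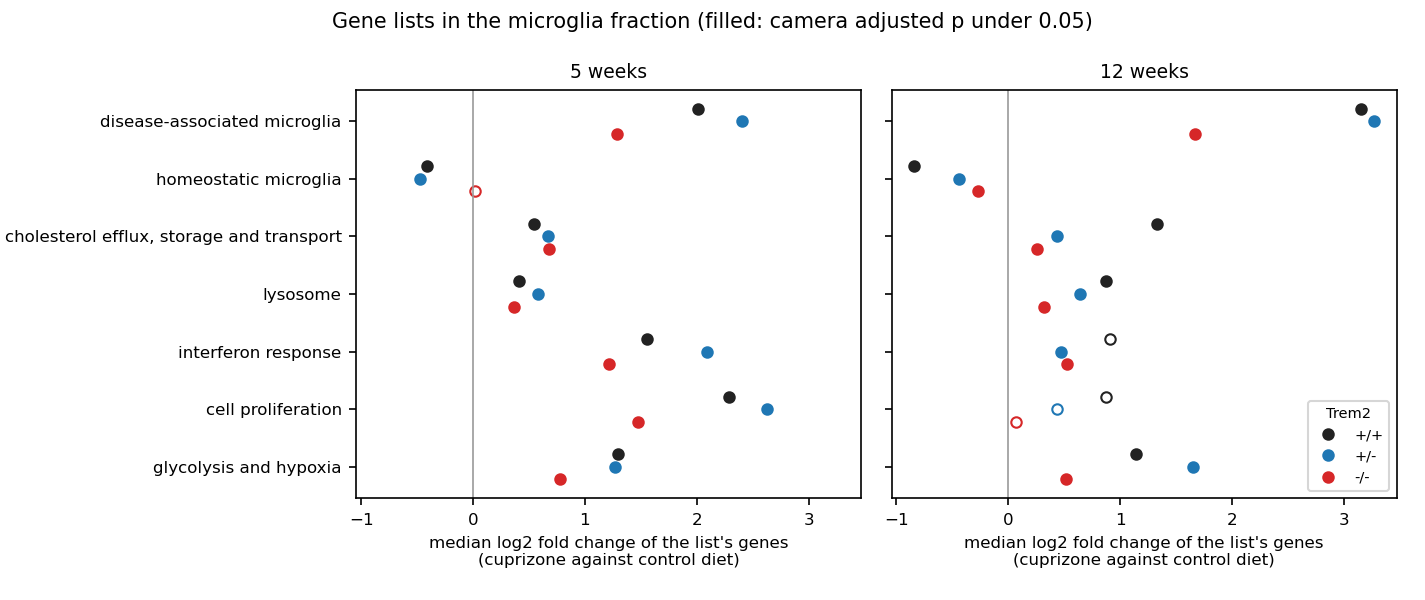
Median log2 fold change of 7 gene lists in microglia, cuprizone against control chow, at 5 and 12 weeks in wild type (+/+), heterozygotes (+/-) and knockouts (-/-); filled points passed camera with a preset correlation (adjusted p under 0.05). At 12 weeks the disease-associated list lies at 3.15, 3.27 and 1.67.

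Because the wild-type control group at 12 weeks held 2 animals, knockouts were also compared with heterozygotes, a comparison added after the data were seen. On cuprizone knockout microglia were lower than heterozygous ones in Apoe (-2.09 ± 0.25, adjusted p = 1.51e-07), Lpl (-4.42 ± 0.50, 2.85e-06), Axl (-2.67 ± 0.45, 0.000295) and Itgax (-3.40 ± 0.64, 0.0045; n = 3 and 4). So were Cst7 (249 ± 38.9 against 1003 ± 232 CPM, 0.0334), the cytokine Il1a (-2.24 ± 0.36, 9.4e-05) and Ch25h, which makes 25-hydroxycholesterol (-6.30 ± 1.44, 0.028). They were higher in Tmem119 (1.03 ± 0.24, 0.0226), S100a4, a calcium-binding protein of monocytes (3.16 ± 0.69, 0.0121), and Mbp (281 ± 174 against 103 ± 23.6 CPM, 0.0311). Without knockout 9542 the difference in Mbp was 0.76 (adjusted p = 0.376). Among 21 disease-associated genes 9 were lower, 16 adjusted over the list alone (median -1.76), and of 16 inflammatory genes 4 and 6 (-0.64). Of 28 lysosomal genes 2 and 4 were lower (-0.35), and of 19 efflux genes 2 and 5 (-0.69). In this order the lists had adjusted p = 6.04e-07, 0.0211, 0.0136 and 0.0159 with an estimated correlation. Neutrophil markers were higher by a median of 4.91, or 4.23 with genes at 0 in a group held at the floor (1 called, 8 of 9 adjusted over the list alone) and myelin genes by 1.24, with adjusted p = 0.219 and 0.235 with an estimated correlation. EdgeR called 42 genes higher and 106 lower, and DESeq2 447. The mitochondrial share differed as well, with a highest value of 3.17% in knockouts and a lowest of 4.05% in heterozygotes. The total was 36 without knockout 981, and 59, 64 and 91 without heterozygotes 2476, 9469 and 6296. It was 44 with the noncoding share as a covariate and 53 without the libraries beyond 30 on principal component 1. The matching interaction called 18 genes, all with a lower diet effect in knockouts, among them Apoe (-1.96 ± 0.33, 0.00239), Lpl (-2.91 ± 0.62, 0.0448), Ccl6, a chemokine (-2.16 ± 0.48, 0.0448), Il1a (-2.16 ± 0.48, 0.0408) and Cxcl2 (-2.33 ± 0.50, 0.03). The disease-associated list had 3 genes called, 8 adjusted over the list alone and a median of -1.57 (adjusted p = 0.00428 with an estimated correlation). DESeq2 called 108 genes (38 with a greater effect in knockouts), limma 27 and edgeR with no count filter 82. The count of 18 was 5 with the noncoding share as a covariate and 9 without the libraries beyond 30 on principal component 1. It was 3 without knockout 981, 5 and 10 without heterozygotes 2476 and 6296 on cuprizone, 10, 11 and 31 without control heterozygotes 7674, 9463 and 944, 10 without control knockout 1744 or 8635, and 38 without knockout 1748 on cuprizone.

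In the nonmicroglia fraction at 5 weeks cuprizone raised a small set of stress genes in all 3 genotypes. Gdf15, a stress-induced growth factor (ENSMUSG00000038508.7, chromosome 8, 70629393 to 70632456), rose by 4.56 ± 0.70 in wild type, 6.31 ± 0.76 in heterozygotes and 4.67 ± 0.71 in knockouts (adjusted p = 0.000613, 2.85e-06 and 0.000401; n = 3 and 3 in each). Ddit3, the stress transcription factor CHOP (ENSMUSG00000025408.15, chromosome 10, 127290774 to 127296288), rose by 2.59 ± 0.41, 2.71 ± 0.41 and 2.28 ± 0.40 (adjusted p = 0.000344, 4.03e-05 and 0.00128). Nupr1, a stress-induced nuclear protein, rose in wild type (3.25 ± 0.64) and heterozygotes (3.89 ± 0.64). In heterozygotes the cell cycle inhibitor Cdkn1a and the mitochondrial folate enzyme Mthfd2 (2.99 ± 0.62) rose, and Arap2, a regulator of small GTPases, in knockouts (1.73 ± 0.29, adjusted p = 0.000401). The other genes called in knockouts were Lrrc8b, a volume-regulated anion channel subunit (2.10 ± 0.40), and the uncharacterised 2410006H16Rik. Of 20 integrated stress response genes 2, 4 and 2 rose in the 3 genotypes, and 7, 7 and 5 adjusted over the list alone. The medians were 0.92, 1.17 and 0.87 (adjusted p = 0.000204, 7.33e-05 and 1.37e-05 with an estimated correlation). Astrocyte markers were lower as a list, with medians of -0.53, -0.54 and -0.24, 0 genes called by edgeR in any genotype and 0, 1 and 0 adjusted over the list alone (adjusted p = 0.0189, 0.0134 and, in knockouts, 0.352 with an estimated correlation). Myelin genes did not pass as single genes. Mog, a myelin surface glycoprotein, was at 97.6 ± 17.2 against 178 ± 62.1 CPM in wild type, 137 ± 86.2 against 249.6 ± 99.3 in heterozygotes and 167 ± 26.6 against 186 ± 50.9 in knockouts. In heterozygotes the myelin list had a median of -0.37 (adjusted p = 0.548 with an estimated correlation). EdgeR called 7, 10 and 5 genes up and 0, 0 and 0 down, DESeq2 48, 26 and 18 in all, and limma 28, 19 and 6. In order, 993, 817 and 488 genes had an unadjusted p under 0.05. The wild-type count was 3 without animal 2474 or 5512 and 4 without 1930 or 9144. The heterozygote count was 4 without 4352 or 8042, 5 without 1745 or 9546 and 6 without 1106, and the knockout count 3 without 1104.

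At 12 weeks cuprizone raised Gdf15 and Ddit3 in each genotype of the nonmicroglia fraction as well. Gdf15 rose by 4.20 ± 0.81 in wild type, 4.09 ± 0.58 in heterozygotes and 4.59 ± 0.69 in knockouts (adjusted p = 0.0161, 3.72e-05 and 0.000219). In the same order Ddit3 rose by 2.90 ± 0.49, 2.26 ± 0.35 and 2.67 ± 0.41 (0.000929, 3.72e-05 and 8.25e-05). Syt4, a synaptotagmin of secretory vesicles, rose by 4.44 ± 0.64, 5.15 ± 0.49 and 4.66 ± 0.54 (2.11e-05, 2.76e-12 and 1.33e-08; n = 3 and 2, 4 and 4, 3 and 3). Atf5, a transcription factor of the mitochondrial stress response, rose in heterozygotes (2.17 ± 0.38) and knockouts (3.19 ± 0.46). Aldh1l2, a mitochondrial folate enzyme, was at 0 in both wild-type control libraries and 43.6 ± 14.3 CPM on cuprizone. Of 20 integrated stress response genes 3, 4 and 3 rose. Adjusted over the list alone 7 rose and 1 fell in wild type, 7 rose in heterozygotes and 6 in knockouts. The medians were 0.54, 1.09 and 0.89 (adjusted p = 0.00094, 1.9e-05 and 0.00111 with an estimated correlation). Ntsr2, an astrocyte receptor, fell in wild type by 2.34 (adjusted p = 0.00872), as did the proteoglycan Bcan, the microtubule protein Map1a and the synaptic vesicle protein Sv2a. The precursor proteoglycan Cspg5 fell in heterozygotes by 1.76 (6.27e-05). The astrocyte list had medians of -0.47, -0.54 and -0.56, with 4, 3 and 3 genes down adjusted over the list alone (adjusted p = 0.129, 0.0373 and 0.164 with an estimated correlation). Cholesterol biosynthesis genes fell in wild type (0 of 23 called by edgeR, 2 adjusted over the list alone, median -0.80, adjusted p = 0.0397 with an estimated correlation). Ependymal and choroid plexus genes were lower on cuprizone in heterozygotes (median -1.38, 3 of 8 down adjusted over the list alone, adjusted p = 0.0728 with an estimated correlation). Mog was at 247 ± 70.8 against 307 ± 136 CPM in wild type, 226 ± 129 against 352 ± 49.0 in heterozygotes and 334 ± 195 against 264 ± 88.0 in knockouts. The myelin list median in wild type was -0.97 with 0 genes called and 5 of 19 down adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). EdgeR called 10 up and 4 down in wild type, 22 and 2 in heterozygotes and 5 and 1 in knockouts, and DESeq2 92, 122 and 29 in all. Limma called 1, 49 and 7. The wild-type count was 141 without control animal 9145, 1 without control animal 1932, and 7 and 3 without cuprizone animals 1746 and 3917. The heterozygote count was 13 without control animal 943.

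**Figure D4:**
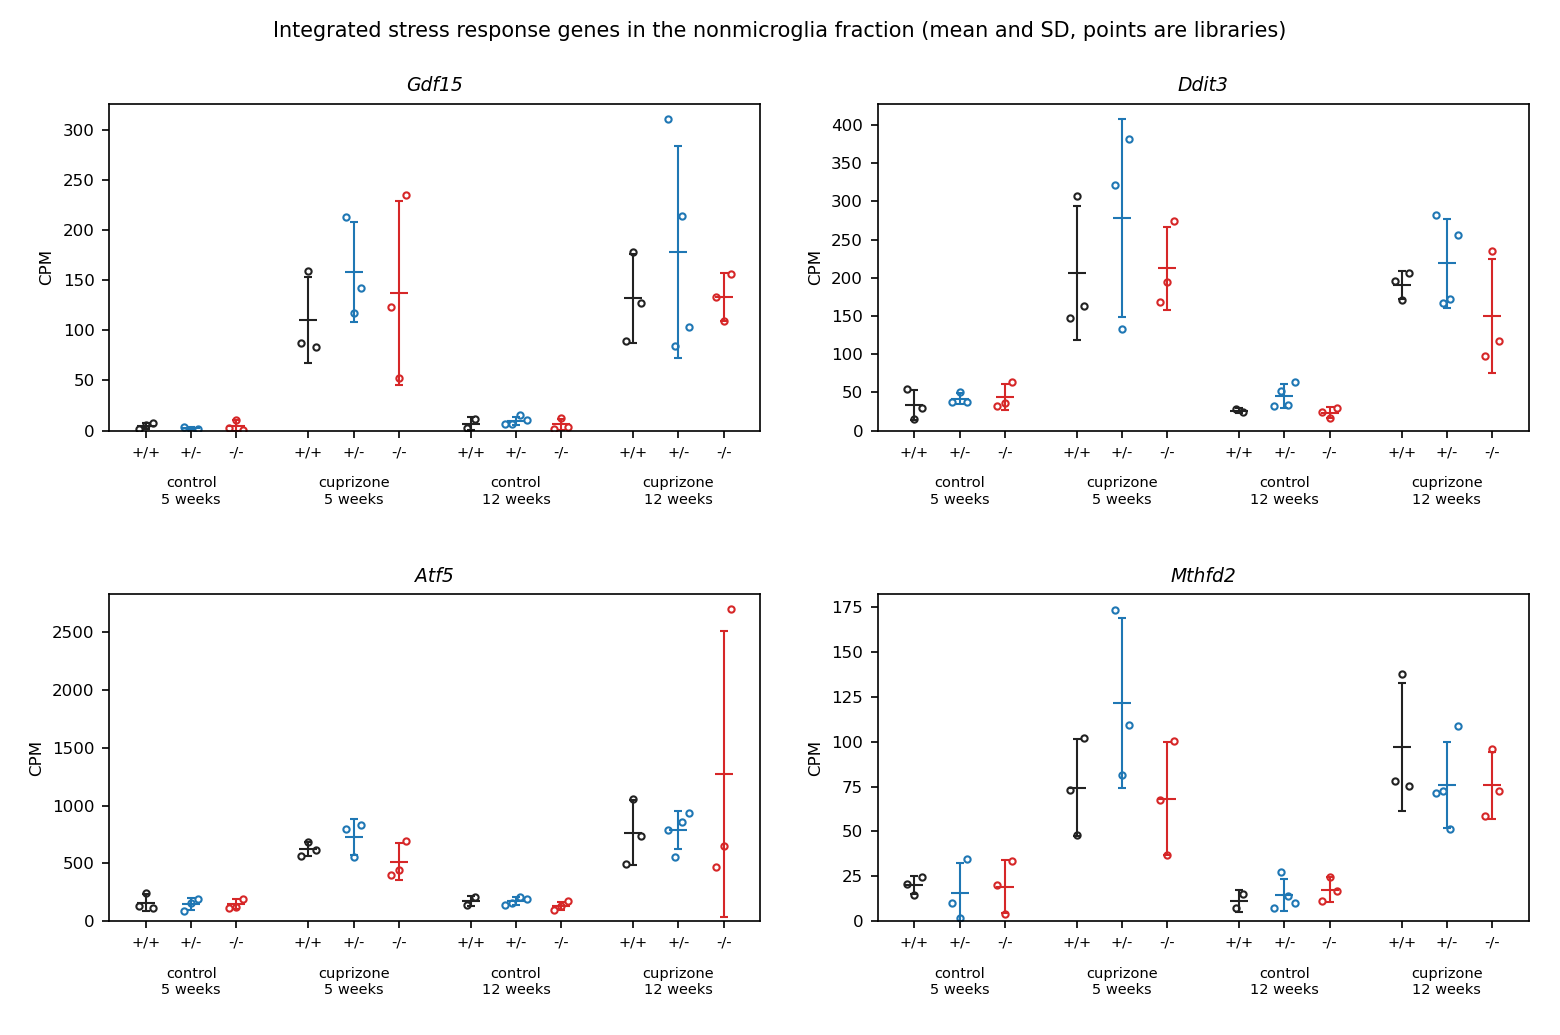
Gdf15, Ddit3, Atf5 and Mthfd2 in the nonmicroglia fraction, in CPM, by diet, weeks and genotype (+/+ wild type, +/- heterozygote, -/- knockout); points are libraries, bars the mean and SD. On control chow Gdf15 means lie between 2.07 ± 1.68 and 9.66 ± 4.31 CPM, and on cuprizone between 109.9 ± 43.0 and 178 ± 105 (SD, n = 3 or 4).

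By edgeR with the count filter, genotype left no called gene in the nonmicroglia fraction. EdgeR called 0 between knockout and wild type on control chow and 0 on cuprizone at 5 weeks, with 795 and 414 genes at an unadjusted p under 0.05 (DESeq2 9 and 2, limma 4 and 0). At 12 weeks it called 0 and 0 (707 and 724 unadjusted, DESeq2 5 and 7, limma 0 and 0). Between heterozygotes and wild type it called 0 and 0 at 5 weeks (1055 and 533 unadjusted, DESeq2 16 and 2, limma 0 and 2). At 12 weeks the counts were 0 and 0 (969 and 1041 unadjusted, DESeq2 8 and 9, limma 0 and 0). The interaction of diet and knockout called 0 at 5 and 0 at 12 weeks (660 and 950 unadjusted, DESeq2 2 and 6, limma 1 and 0). With no count filter the knockout counts on control chow and cuprizone were 13 and 4 at 5 weeks and 2 and 5 at 12 weeks. Those of heterozygotes were 18 and 4, and 10 and 4. Without wild-type control animal 9145 the 12-week counts on control chow were 34 for knockouts and 65 for heterozygotes and the interaction count was 43. Without control knockout 8635 the knockout and interaction counts were 1 each, and without cuprizone knockout 981 the knockout count on cuprizone was 1. At 5 weeks the knockout count on control chow was 2 and 1 without wild-type animals 309 and 5512. Gene levels on cuprizone at 12 weeks were 3522 ± 988 CPM in knockouts, 2935 ± 547 in heterozygotes and 2756 ± 554 in wild type for Mbp (n = 3, 4 and 3). In the same order they were 68.3 ± 36.5, 47.6 ± 28.8 and 34.2 ± 2.15 for Serpina3n, a protease inhibitor of reactive astrocytes, and 17.9 ± 13.1, 2.81 ± 4.02 and 8.31 ± 8.90 for the astrocyte filament Gfap. For the precursor receptor Pdgfra they were 13.1 ± 15.8, 8.89 ± 8.30 and 11.7 ± 7.48, and 579.5 ± 144, 501 ± 96.0 and 562 ± 172 for the endothelial claudin Cldn5. Of the gene lists, no genotype or interaction call in this fraction held with an estimated correlation. The lowest such adjusted p was 0.0833, for endothelial and mural markers in knockouts on control chow at 5 weeks, whose medians were -0.58 and -0.90. In the interaction at 12 weeks myelin genes had a median of 0.91 with 19 of 19 above 0 and 3 called adjusted over the list alone (adjusted p = 0.795 with an estimated correlation).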

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

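The tests of microglial dilution and of dissociation stress, and all comparisons of knockouts with heterozygotes, were chosen only after the results were seen. The other tests were planned or had their outcome stated beforehand.

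Disease-associated genes were lower in knockout than in wild-type microglia on cuprizone at 12 weeks, with a list median of -2.07. Library structure as the whole cause is argued against: with the noncoding share as a covariate the median was -2.06. Fewer sorted microglia would lower all microglial transcripts alike, and their marker list had a median of 0.339. In wild type the list was lower on cuprizone (10.86 against 11.24 log2 CPM), so it may mask some dilution. A genotype-linked change in cell state is a hypothesis, as the 3 knockout and 3 wild-type animals may differ otherwise.

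Myelin transcripts were higher in knockout than in wild-type microglia on cuprizone at 12 weeks, with a list median of 1.33 (adjusted p = 0.285 with an estimated correlation). Carry-over from the whole nonmicroglia fraction has the values it needs. That fraction's 100 most abundant transcripts far lower in microglia, outside the oligodendrocyte and astrocyte lists, had a median of 0.903 (quartiles 0.399 and 1.44). Of them 91 lay above 0, and 1 passed the test. The rise may therefore be carry-over, and uptake of myelin with its RNA by knockout microglia was not tested and stays open. Animals 981 and 9542 had the highest means of these transcripts in the group (4.85 and 4.39 log2 CPM), and the sort for Cd11b would remove oligodendrocytes.

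Integrated stress response genes rose with cuprizone in the nonmicroglia fraction in 6 of 6 diet comparisons. Library structure is argued against only as far as the noncoding share measures it. With that share as a covariate the list was called up in 6 of 6 comparisons. Stress of tissue dissociation is argued against as the whole cause, since within 6 of 6 comparisons the list rose beyond the immediate early and heat shock list by more than the spread over animals. The smallest such excess was 0.857 in log2 (2 standard errors 0.564). The highest immediate early median and the lowest stress response median, 0.371 and 0.539, differed by less than the spread among genes. A response of the cells to the diet itself is a candidate explanation and was not tested apart.

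In groups of 4, the gap of 1 animal to the nearest other took most of the group's range in 6 cases. Chance gives about 1 such value in 20 tests, and 170 were made over 4 groups, so 6 is no more than chance gives. In microglia of heterozygotes on control chow at 12 weeks, the precursor list of animal 7674 was at 0.703 (log2 CPM). On cuprizone, the cholesterol biosynthesis list of animal 9469 was at 2.45, its efflux list at 5.61 and the precursor list of animal 6296 at 2.03, in a group with little spread (1.91 ± 0.0840, SD, n = 4). In the nonmicroglia fraction of heterozygotes at 12 weeks, the astrocyte list of control animal 944 was at 8.57 and the mitochondrial share of cuprizone animal 6296 at 9.28%.

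The following were called in tests of the interaction of diet and genotype, genes by edgeR and lists by camera with the preset correlation. Values are log2 differences or list medians, with a list's adjusted p with an estimated correlation in brackets, and most lists did not pass in that second setting. In microglia at 5 weeks, knockout against wild type, Lpl was at -4.15 (adjusted p = 0.0101 by edgeR). The lists were disease-associated at -0.76 (0.26), homeostatic at 0.22 (0.26), immediate early at 0.35 (0.508), microglia at 0.22 (0.26), border macrophage at 1.17 (0.26) and neutrophil at 2.06 (0.508). At 12 weeks Calhm2 was at -3.34, Cxcl2 at -3.33, Prcp at -3.62 and Hspe1 at -4.83. The lists were disease-associated at -1.63 (0.0408), homeostatic at 0.59 (0.0615), cholesterol efflux at -1.14 (0.0408), lysosome at -0.50 (0.0615), inflammatory at -0.83 (0.273), immediate early at -0.67 (0.515), myelin at 2.23 (0.259) and astrocyte at 1.44 (0.515). Between knockout and heterozygote at 12 weeks, Cd52 was at -1.60, Apoe at -1.96, Cstb at -2.33, Lpl at -2.91, Ccl6 at -2.16, Phlda1 at -3.06, Zcrb1 at -2.08, Tmem176a at -3.25 and Rps26 at -1.80. Smarcc2 was at -2.29, Il1a at -2.16, Ndufb11 at -3.09, Bola2 at -2.27, Cxcl2 at -2.33, Tmem256 at -1.78 and Ubxn1 at -2.49. Dkk2 was at -9.78 and Pianp at -6.79, fitted values that rest on groups with few or 0 counts and are no bounds. The lists there were disease-associated at -1.57 (0.00428), lysosome at -0.15 (0.289), inflammatory at -0.70 (0.0401), immediate early at -0.34 (0.475), myelin at 1.17 (0.399), astrocyte at 1.07 (0.436), ependymal at 2.23 (0.289) and neutrophil at 4.04 (0.448). In the nonmicroglia fraction, knockout against wild type, immediate early genes were at 0.45 (0.813) and endothelial at 0.51 (0.813) at 5 weeks, and myelin at 0.91 (0.795) and endothelial at -0.56 (0.795) at 12 weeks.

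Other splits of the compared libraries were counted. For the comparison of fractions, only the real split of 100 gave as many calls (3596, highest other 0), which argues against chance without excluding it. Of the others, the 13 that part both fractions of each animal (highest 0) are too few for a share under 0.05. With 35 splits, only the real one gave as many calls for the heterozygote diet effect at 12 weeks, in microglia (359, highest other 2) and in the nonmicroglia fraction (24, highest other 2). The same held in microglia on cuprizone at 12 weeks for heterozygotes against wild type (17, highest other 7) and knockouts against heterozygotes (148, highest other 11). A share of 1 in 35 is under 0.05 but is the lowest that 35 splits allow. It was not adjusted over the comparisons, so it argues against chance in each alone without excluding it. In the nonmicroglia fraction all 35 splits of heterozygotes against wild type on cuprizone gave at least the real 0, and the highest gave 6. In the interaction with heterozygotes 2 of 100 splits, the real one included, gave at least the real 18, and the other of them gave 54. Genotype was shuffled within each diet, so that a genotype difference on cuprizone can enter such a split, and the cause was not tested. In the interaction at 5 weeks 17 of 100 splits gave at least 1 call in microglia (highest 10, of untested cause). In the other fraction 100 of 100 gave at least the real 0 (highest 1), so chance is not excluded in either. With 3 against 3 animals there are 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, reached its count in microglia for the diet effect at 5 weeks in wild type (20, highest other 0), heterozygotes (39 and 1) and knockouts (8 and 1), at 12 weeks in knockouts (4 and 1), and for knockouts against wild type on control chow (1 and 0) and cuprizone (11 and 0) at 5 weeks and on cuprizone at 12 weeks (62 and 1). It did so in the nonmicroglia fraction for the diet effect at 5 weeks in wild type (7 and 0), heterozygotes (10 and 0) and knockouts (5 and 0), and at 12 weeks in knockouts (6 and 0). The real count was 0, which all 10 splits reach, for heterozygotes against wild type in microglia at 5 weeks on control chow (highest other 0) and cuprizone (1), and in the nonmicroglia fraction for knockouts against wild type at 5 weeks on control chow (0) and cuprizone (0) and at 12 weeks on cuprizone (0), and for heterozygotes at 5 weeks on control chow (1) and cuprizone (0). Comparisons with the 2 wild-type control animals at 12 weeks have no such count.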

How the results depend on the processing

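The alternatives with the share of noncoding counts as a covariate and without the libraries beyond 30 on principal component 1, and both comparisons of knockouts with heterozygotes, were chosen after the data were seen, and the other alternatives were planned. A count of called genes is printed here where it moved by more than 1.5 times, and the cause was not tested except where named.

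Directions were stable: no named gene that passed the test turned its direction past the threshold under any of the settings run. DESeq2's size factors left 1525 named gene results on their side of the threshold, took 12 below it and brought 5 above it. The numbers were 1324, 0 and 75 with DESeq2's test (missing values left out), 1308, 86 and 24 with limma, and 1434, 8 and 100 without the filter. They were 1512, 28 and 2 without sex, 1342, 74 and 2 with the noncoding share, 1325, 79 and 14 without the distant libraries, and 10394, 643 and 44 over all fits that left out 1 library.

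In the fraction comparison, with the animal as a block in a paired fit, 1560 genes were higher and 1977 lower in microglia, 3537 in all against 3596 with week and sex as covariates. Of the genes named there 123 stayed on their side of the threshold and 1 lost its call. Leaving out 1 library gave 3454 to 3830.

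With DESeq2's test, the diet effect in microglia gave at 5 weeks 79 in wild type, 107 in heterozygotes and 36 in knockouts, and at 12 weeks 362 in wild type, 605 in heterozygotes and 37 in knockouts. Knockouts against wild type in microglia gave 3 on control chow and 34 on cuprizone at 5 weeks, and 11 and 193 at 12 weeks. Heterozygotes against wild type in microglia gave 1 on control chow and 1 on cuprizone at 5 weeks, and 21 and 121 at 12 weeks. Knockouts against heterozygotes in microglia gave 447 on cuprizone at 12 weeks. The interaction of diet and knockout in microglia gave 3 at 5 weeks and 132 at 12 weeks against wild type, and 108 at 12 weeks against heterozygote. The diet effect in the nonmicroglia fraction gave at 5 weeks 48 in wild type, 26 in heterozygotes and 18 in knockouts, and at 12 weeks 92 in wild type, 122 in heterozygotes and 29 in knockouts. Knockouts against wild type in the nonmicroglia fraction gave 9 on control chow and 2 on cuprizone at 5 weeks. Counts at 12 weeks were 5 and 7. Heterozygotes against wild type in the nonmicroglia fraction gave 16 on control chow and 2 on cuprizone at 5 weeks. Counts at 12 weeks were 8 and 9. The interaction of diet and knockout in the nonmicroglia fraction gave 2 at 5 weeks against wild type and 6 at 12 weeks against wild type.

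With limma and quality weights, the diet effect in microglia gave at 5 weeks 86 in wild type, 70 in heterozygotes and 2 in knockouts, and at 12 weeks 7 in knockouts. For knockouts against wild type, microglia gave 40 on cuprizone at 5 weeks, 8 on control chow at 12 weeks and 110 on cuprizone at 12 weeks. For heterozygotes against wild type, microglia gave 1 on control chow and 2 on cuprizone at 5 weeks, and 1 and 46 at 12 weeks. For the interaction of diet and knockout, microglia gave 4 at 5 weeks against wild type and 0 at 12 weeks against wild type. The diet effect in the nonmicroglia fraction gave at 5 weeks 28 in wild type and 19 in heterozygotes, and at 12 weeks 1 in wild type and 49 in heterozygotes. For knockouts against wild type, the nonmicroglia fraction gave 4 on control chow at 5 weeks. For heterozygotes against wild type, the nonmicroglia fraction gave 2 on cuprizone at 5 weeks. For the interaction of diet and knockout, the nonmicroglia fraction gave 1 at 5 weeks against wild type.

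With no count filter, the diet effect in microglia gave at 5 weeks 67 in wild type, 90 in heterozygotes and 61 in knockouts, and at 12 weeks 35 in knockouts. Knockouts against wild type in microglia gave 11 on control chow and 32 on cuprizone at 5 weeks, and 69 and 142 at 12 weeks. Heterozygotes against wild type in microglia gave 8 on control chow at 5 weeks, 73 on control chow at 12 weeks and 72 on cuprizone at 12 weeks. Knockouts against heterozygotes in microglia gave 279 on cuprizone at 12 weeks. The interaction of diet and knockout in microglia gave 9 at 5 weeks and 149 at 12 weeks against wild type, and 82 at 12 weeks against heterozygote. The diet effect in the nonmicroglia fraction gave at 5 weeks 34 in wild type, 25 in heterozygotes and 12 in knockouts, and at 12 weeks 50 in wild type, 73 in heterozygotes and 27 in knockouts. Knockouts against wild type in the nonmicroglia fraction gave 13 on control chow and 4 on cuprizone at 5 weeks. Counts at 12 weeks were 2 and 5. Heterozygotes against wild type in the nonmicroglia fraction gave 18 on control chow and 4 on cuprizone at 5 weeks. Counts at 12 weeks were 10 and 4. Genes with few counts are tested in that setting, and which genes entered was not examined.

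With DESeq2's size factors, knockouts against wild type in microglia gave 1 on control chow at 12 weeks. Without sex in the model, heterozygotes against wild type in microglia gave 10 on cuprizone at 12 weeks. With the noncoding share, the diet effect in microglia gave at 12 weeks 38 in wild type. For knockouts against wild type, microglia gave 1 on control chow at 12 weeks. For knockouts against heterozygotes, microglia gave 44 on cuprizone at 12 weeks. For the interaction of diet and knockout, microglia gave 2 at 12 weeks against wild type and 5 at 12 weeks against heterozygote. The diet effect in the nonmicroglia fraction gave at 5 weeks 13 in wild type. Without the distant libraries, the diet effect in microglia gave at 5 weeks 62 in heterozygotes, and at 12 weeks 25 in wild type. As to knockouts against wild type, microglia gave 2 on control chow at 5 weeks. As to knockouts against heterozygotes, microglia gave 53 on cuprizone at 12 weeks. As to the interaction of diet and knockout, microglia gave 1 at 12 weeks against wild type and 9 at 12 weeks against heterozygote. The diet effect in the nonmicroglia fraction gave at 5 weeks 4 in wild type.

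With the correlation estimated from the data, 78 of 957 list tests passed in place of 195. The number was 194 with DESeq2's size factors, 183 without the filter and 190 without sex. The estimated correlation replaces a preset value of 0.01, so a list whose members move together loses weight.

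Each fit that left out 1 library kept the rest of the model. Where 1 control animal stayed in a group, it was assumed to vary like the other groups. Trem2 in knockouts against wild type on control chow at 5 weeks ranged from -2.60 to -1.72. Leaving out 1 library, the diet effect in microglia gave at 5 weeks 8 to 23 in wild type, 13 to 36 in heterozygotes and 4 to 11 in knockouts, and at 12 weeks 14 to 66 in wild type, 261 to 347 in heterozygotes and 2 to 7 in knockouts. As to knockouts against wild type, microglia gave 0 to 2 on control chow at 5 weeks, 6 to 10 on cuprizone at 5 weeks, 1 to 6 on control chow at 12 weeks and 33 to 66 on cuprizone at 12 weeks. As to heterozygotes against wild type, microglia gave 0 to 0 on control chow at 5 weeks, 0 to 0 on cuprizone at 5 weeks, 0 to 0 on control chow at 12 weeks and 3 to 30 on cuprizone at 12 weeks. As to knockouts against heterozygotes, microglia gave 36 to 170 on cuprizone at 12 weeks. As to the interaction of diet and knockout, microglia gave 0 to 2 at 5 weeks against wild type, 1 to 37 at 12 weeks against wild type and 3 to 38 at 12 weeks against heterozygote. The diet effect in the nonmicroglia fraction gave at 5 weeks 3 to 6 in wild type, 4 to 10 in heterozygotes and 3 to 5 in knockouts, and at 12 weeks 1 to 141 in wild type, 13 to 32 in heterozygotes and 5 to 8 in knockouts. As to knockouts against wild type, the nonmicroglia fraction gave 0 to 2 on control chow at 5 weeks, 0 to 0 on cuprizone at 5 weeks, 0 to 34 on control chow at 12 weeks and 0 to 1 on cuprizone at 12 weeks. As to heterozygotes against wild type, the nonmicroglia fraction gave 0 to 0 on control chow at 5 weeks, 0 to 0 on cuprizone at 5 weeks, 0 to 65 on control chow at 12 weeks and 0 to 0 on cuprizone at 12 weeks. As to the interaction of diet and knockout, the nonmicroglia fraction gave 0 to 0 at 5 weeks against wild type and 0 to 43 at 12 weeks against wild type.

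In data simulated at the depths of these libraries, with 3 animals against 3, most changes of 2-fold and 4-fold were missed. Of genes changed 2-fold, 4-fold, 8-fold and 16-fold, 2%, 38%, 52% and 68% were recovered in a microglia comparison and 0%, 26%, 58% and 70% in the other fraction. Groups of 2 or 4 animals were not simulated. A count of 0 therefore does not show that groups were alike.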

Other observations

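Only the test of all raised genes had its outcome stated beforehand, and the gene sets were taken from heterozygotes after their calls were seen.

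Genes that changed in heterozygous microglia at 12 weeks were followed in the other genotypes. The 265 genes that rose had a median diet effect of 0.961 in wild type and 0.373 in knockouts at 12 weeks, and without the disease-associated list the remaining 247 had 0.930 and 0.330. The 94 genes that fell had -0.663 in wild type and 0.0186 in knockouts. At 5 weeks the raised genes had 0.827 and 0.556 and the lowered ones -0.487 and -0.397, closer together than at 12 weeks. The hypothesis that this set responds less in knockouts than in wild type at 12 weeks was tested with camera and an estimated correlation on the interaction. Camera in limma gave unadjusted p-values of 0.00473 for the raised genes, 0.00744 without the disease-associated list and 0.000149 for the lowered ones. The response of knockout microglia at 12 weeks may therefore be smaller over a wider set of genes than the disease-associated list, which was not tested at 5 weeks. The test shares the wild-type controls, of which there were 2.

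Mitochondrial transcripts in microglia made up 4.30 ± 0.244% of counts in heterozygotes on cuprizone at 12 weeks (SD, n = 4), with single libraries between 4.05% and 4.56%. The rRNA and coding genes mt-Rnr1, mt-Nd5 and mt-Cytb were among the genes higher there than in wild type on cuprizone. Along principal component 1, which held 17.1% of the variance in microglia and 12.5% in the nonmicroglia fraction, 4 microglia libraries (animals 7674, 9145, 945 and 981) and 2 nonmicroglia libraries (animals 1930 and 9469) lay beyond 30.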
